A study of Homo sapiens with 6 samples.

How the data were processed

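Gene expression was measured in IMR-32, an established human neuroblastoma cell line, 48 h after transfection with the empty plasmid pCMV, with pCMV carrying DPP3 or with pCMV carrying SQSTM1. Each of the 3 groups had 2 arrays, which the series describes as duplicate transfections, and nothing says whether the cells came from separate cultures. The p-values therefore measure the spread between these arrays. Total RNA was amplified and labelled with biotin by the Affymetrix 3' protocol, per the labels' protocols, and hybridised to HG-U133 Plus 2 arrays, per the file headers.

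The deposited table held 1 intensity per probe set and array on a linear scale. GCRMA, a method that corrects background by probe sequence, normalizes by quantiles and summarises the probes of a probe set, is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The deposited intensities ran from 19.7 to 907982 with array medians between 98.4 and 102, and the top lies beyond what a scanner of these arrays reads, so a multiplication by an unstated factor is apparent. If 1 factor was applied to all values, fold changes do not depend on it, which was not tested. The other deposited files were the instrument's run settings, per the file headers. The chip type, the fluidics station and the module were read from them. All 6 arrays shared 1 chip lot, 1 scanner, 1 hybridisation day and 1 scan day. The 2 pCMV arrays were washed on station 2, and all 4 arrays of the DPP3 and SQSTM1 groups on station 1. Station and plasmid thus cannot be told apart in comparisons with pCMV, whereas the SQSTM1 and DPP3 groups shared a station.

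From these intensities, log2 was taken with a floor of 1, which no value reached. The design had assumed log2 values and provided for this step. Of 54675 probe sets, 62 were array controls, 41091 carried exactly 1 gene symbol in the platform annotation, 1801 carried several and 11721 carried none. Probe sets with several symbols or none were not named. Symbols were looked up by gene identifier in the RefSeq table of assembly GRCh38.p14, where 41037 of the 41091 matched and 0 symbols changed. No coordinates are given because the files name no genome build. For each gene the probe set with the highest mean over the 6 arrays was used. The planned filter, a log2 value above 4 in at least 2 arrays, removed 0 of 19775 genes, because the deposited values begin above it.

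Genes were tested with limma 3.58.1 in R 4.3.3. The model had 1 mean per group over all 6 arrays, which gave 3 residual degrees of freedom, and eBayes with its default prior. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison at a threshold of 0.05. The 3 comparisons were DPP3 against pCMV, SQSTM1 against pCMV, and SQSTM1 against DPP3. The number of arrays limits the precision. Errors of fold changes are the moderated standard errors of limma, and errors of levels are the SD of 2 arrays.

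Before the data were examined, 21 gene lists were fixed, with 585 genes, of which 541 were measured. They cover ARE targets, glutathione metabolism, thioredoxin and oxidant detoxification, pentose phosphate and NADPH supply, iron and haem handling, the heat shock response, the unfolded protein response, the ATF4 and amino acid response, autophagy and lysosome, the proteasome, NF-kappaB targets, the interferon response, p53 targets, the cell cycle, immediate early genes, hypoxia and glycolysis, cholesterol synthesis, metallothioneins and metal response, noradrenergic neuroblast markers, mesenchymal and Schwann-like cell markers, and housekeeping reference genes. DPP3 and SQSTM1 were left out of every list. Lists share members, so their calls are not independent. GCLC, GCLM and GSR, for example, are in both the ARE and the glutathione list. Each list was tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 21 lists of a comparison. Camera compares a list with all other genes, and its direction rests on moderated statistics, so it can differ in sign from the median fold change. Camera with an estimated correlation and fry were the alternatives. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

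The genes named were also set by a rule fixed at that time. It took both plasmid genes, and the 6 reference ARE genes NQO1, HMOX1, GCLC, GCLM, TXNRD1 and SRXN1. It took up to 10 rises and 10 falls past the threshold whose groups did not overlap, and the 10 smallest p-values where fewer than 5 genes passed. From each list it took up to 4 members past the threshold or, where none passed, the member with the smallest p. It also took up to 5 genes in each direction that passed in both comparisons with pCMV, of which there were 0 here.

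The scripts were tested on simulated data with each gene's mean over the arrays and its residual SD, and with 200 changed genes among those above log2 8. Among 19775 genes, 2-fold changes were recovered for 49.3% of the changed genes in DPP3 against pCMV, 46.9% in SQSTM1 against pCMV and 47.2% in SQSTM1 against DPP3. For 8-fold changes these shares were 92.5%, 91.2% and 91.3%. On average 8.15, 8.65 and 8.95 unchanged genes were called per simulation. These shares hold for 200 changed genes plus a shifted list. Where fewer genes change, the adjusted threshold is harder to reach, so the shares may overstate recovery in these data. A list shifted by 0.3 on the log2 scale was called in 20 of 20 simulations of each comparison. Of 400 tests of unshifted lists, 18, 16 and 27 were called. The simulated arrays varied independently, unlike a pair of arrays that deviate together.

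Alternatives fixed in advance were quantile normalization, centring on array medians, no filter and a filter at log2 above 6, all probe sets, the mean of a gene's probe sets, an intensity trend with a robust prior, only the 4 arrays compared, the replicate number as a block, an adjusted p of 0.10, and leaving out each array. A further 5 were chosen after seeing the data, namely a filter at log2 above 8 in at least 2 arrays, which left 9846 genes, a term for the 2 arrays that deviate together, a crossed pairing of the replicates, leaving out both of those arrays, and, for the correlation of the fold changes alone, 1 pCMV array as the control of each plasmid. A station block was planned where a station held more than 1 group. It cannot be fitted against pCMV, and for SQSTM1 against DPP3 the fit of these 4 arrays gives the value within a station.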

Results

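The series belongs to a search for genes that activate the antioxidant response element (ARE), the promoter sequence through which the transcription factor NRF2 switches on genes of oxidant defence. Expression was profiled in IMR-32 neuroblastoma cells 48 h after transfection with the empty plasmid pCMV, with DPP3 or with SQSTM1, on 2 arrays per group. DPP3 encodes dipeptidyl peptidase 3, a zinc-dependent peptidase, and SQSTM1 encodes p62, an autophagy receptor that binds KEAP1, the inhibitor of NRF2. The comparisons with pCMV ask which genes differ in level when either gene is overexpressed, and the third asks how the plasmids differ from each other.

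Array medians lay between 98.4 and 102 intensity units, and between 36.0% and 36.2% of all probe sets exceeded 256 units. The median SD of log2 intensity between the 2 arrays of a group, over the 9846 genes above log2 8 in at least 2 arrays, was 0.12 for pCMV, 0.10 for DPP3 and 0.06 for SQSTM1. In pCMV replicate 2 and DPP3 replicate 1 the hybridisation spike-ins averaged 15.32 and 14.99 on the log2 scale, against 14.17 to 14.39 in the other 4 arrays. The 18S ribosomal RNA probe sets averaged 7.19 and 9.68 in these arrays and 10.54 to 11.28 in the others. In both of them, 127 of the 9846 genes were higher and 26 were lower than in every other array by more than 0.5. These arrays belong to different groups and widen the spread of the pCMV and DPP3 groups.

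**Figure D1:**
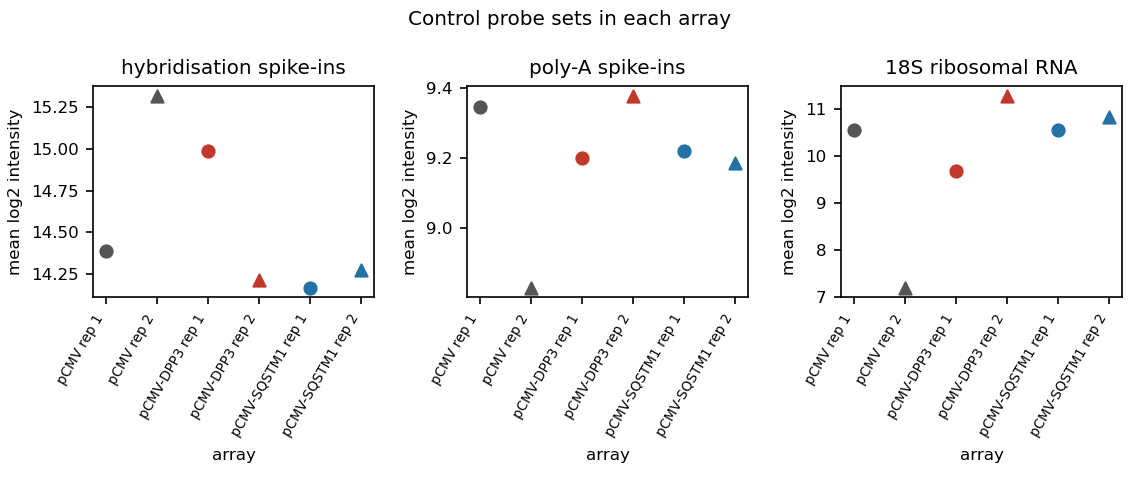
Mean log2 intensity (vertical axes) of the hybridisation spike-ins, the poly-A spike-ins and the 18S ribosomal RNA probe sets in each of the 6 arrays (horizontal axes), coloured by plasmid, with circles for replicate 1 and triangles for replicate 2. The hybridisation spike-ins of pCMV replicate 2 (15.32) and DPP3 replicate 1 (14.99) lie above those of the other 4 arrays, and their 18S values (7.19 and 9.68) lie below.

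In cells given the DPP3 plasmid, DPP3 itself stood 9.87-fold above the empty plasmid, at 15.87 ± 0.06 on the log2 scale against 12.56 ± 0.18 (SD, n = 2). NQO1, a quinone reductase and a classic ARE target, was 3.74-fold higher, at 12.77 ± 0.08 against 10.87 ± 0.09 (SD, n = 2). Other ARE genes were higher by less. SRXN1, which reactivates oxidised peroxiredoxins, had a log2 fold change of 0.50 ± 0.06 (SE), and ME1, a malic enzyme that supplies NADPH, one of 0.43 ± 0.06. TXNRD1, thioredoxin reductase, had 0.35 ± 0.07 (0.17 when its probe sets were averaged), and GCLM, the modifier subunit of the first enzyme of glutathione synthesis, 0.31 ± 0.06. The other TXNRD1 probe set averaged log2 6.07 with pCMV, against 15.83 for the one used. Averaging with so dim a probe set lowers the change and does not contradict it.

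DPP3 differed by 3.30 ± 0.10 (SE) on the log2 scale with the probe set used and by 3.54 ± 0.10 with its other probe set. NQO1 differed by 1.90 ± 0.07, and its other 2 probe sets gave 2.00 ± 0.06 and 1.89 ± 0.21. Among 19775 genes, limma called 0, and the lowest adjusted p was 0.0599, shared by DPP3, NQO1 and ANKRD33B. An unadjusted p under 0.05 was reached by 672 genes, where 989 were expected by chance, and limma with an intensity trend and a robust prior called DPP3 and NQO1. Among the 10 smallest p-values, none of which passed, ANKRD33B had a log2 fold change of 1.00 ± 0.04 and FLVCR1-DT, a non-coding transcript, 0.99 ± 0.06. SMAD3, a mediator of TGF-beta signalling, had -0.73 ± 0.04, but -0.24 when its 4 probe sets were averaged, and MGA, a partner of MAX, had -0.52 ± 0.06, but 0.07 when its probe sets were averaged. ADARB1, an RNA-editing deaminase, had 0.36 ± 0.03, but 0.07 when its 5 probe sets were averaged. ATRNL1 (0.29 ± 0.03, but 0.00082 when its probe sets were averaged) and CARD10 (0.25 ± 0.03, but 0.075), whose intensities lay below log2 8, completed this set with SRXN1.

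Of the ARE targets, 44 were measured and 29 were higher with DPP3 than with pCMV. Over all genes 0 passed in limma, with 11 at an unadjusted p under 0.05. Adjusted over the list alone, 7 rose and 1 fell. The rises were NQO1, TRIM16, SRXN1, ME1, TXNRD1, GCLM and TXN, with log2 fold changes from 1.90 down to 0.21, and the largest after NQO1 was TRIM16, at 0.89 ± 0.17 (SE). The fall was BLVRB, a biliverdin reductase, which fell by 0.39 ± 0.08 at an intensity below log2 8. HMOX1, haem oxygenase 1, differed by 0.21 ± 0.13 at a similarly low intensity, and GCLC, the catalytic partner of GCLM, by 0.22 ± 0.17, where its next brightest probe set gave -0.05 ± 0.08. The list as a whole was shifted up against other genes by camera (median log2 fold change 0.08, adjusted p = 1.1e-08), a call lost at an adjusted p = 0.667 with an estimated correlation. Its median was 0.039 without pCMV replicate 2, 0.024 without DPP3 replicate 2, 0.015 with all probe sets and 0.054 with the mean of probe sets. Fry, which asks whether the members move on balance in 1 direction, gave an adjusted p = 0.407.

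The p53 targets were also shifted up (16 of 21 members higher, median 0.13, adjusted p = 9.7e-05), with an adjusted p = 0.700 with an estimated correlation and a median of 0.0047 without pCMV replicate 2 and 0.048 when probe sets were averaged. None of their members passed, and the smallest p belonged to BAX, which promotes apoptosis, with 0.65 ± 0.14. Glutathione metabolism was shifted up (20 of 35 higher, median 0.03, adjusted p = 0.0206), with an adjusted p = 0.667 with an estimated correlation and a median of 0.0016 without pCMV replicate 2. Its median was 0.0085 with the mean of probe sets and 0.017 with all probe sets. Glutathione metabolism shares GCLC, GCLM and other members with the ARE targets, so its call is not separate from theirs. ME1 (rise) and ME3, a mitochondrial malic enzyme below log2 8 with -0.22 ± 0.04 (fall), passed adjusted over the list alone among the 16 members of pentose phosphate and NADPH supply, as did SRXN1 among the 28 of thioredoxin and oxidant detoxification. In the remaining 18 lists 0 members passed in either way, and over all lists together 0 passed over all genes. The 18 lists not called by camera had adjusted p-values from 0.101 to 0.992. These were thioredoxin and oxidant detoxification, pentose phosphate and NADPH supply, iron and haem handling, the heat shock response, the unfolded protein response, the ATF4 and amino acid response, autophagy and lysosome, the proteasome, NF-kappaB targets, the interferon response, the cell cycle, immediate early genes, hypoxia and glycolysis, cholesterol synthesis, metallothioneins and metal response, noradrenergic neuroblast markers, mesenchymal and Schwann-like cell markers, and housekeeping reference genes. The mean and the camera direction were up and the median was below 0 for the noradrenergic markers and the metallothioneins. Without pCMV replicate 1, all 3 list calls ended although the medians were larger (0.18 with adjusted p = 0.0969 for ARE targets, 0.20 with 0.305 for p53 targets and 0.038 with 0.895 for glutathione metabolism). Without DPP3 replicate 2 the p53 and glutathione calls ended (adjusted p = 0.104 and 0.380, medians 0.080 and 0.019), and without either SQSTM1 array the glutathione call did (adjusted p = 0.0525), as it did with quantile normalization (0.0960) and above log2 8 (0.304).

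With genes above log2 8 only, a filter chosen after seeing the data, DPP3 and NQO1 rose (adjusted p = 0.00392 and 0.0147, ranging over 20 alternatives from 0.00146 to 0.584 and from 0.0147 to 0.596, at log2 fold changes of 3.18 to 3.43 and 1.84 to 1.97). Within station 1, which the SQSTM1 arrays shared, DPP3 and NQO1 were lower by 3.25 ± 0.10 and 0.79 ± 0.07 (SE) with SQSTM1 than with DPP3, and DPP3 differed by 0.05 ± 0.10 between SQSTM1 and pCMV. For genes other than DPP3, the fluidics station and the plasmid cannot be told apart by this comparison alone.

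**Figure D2:**
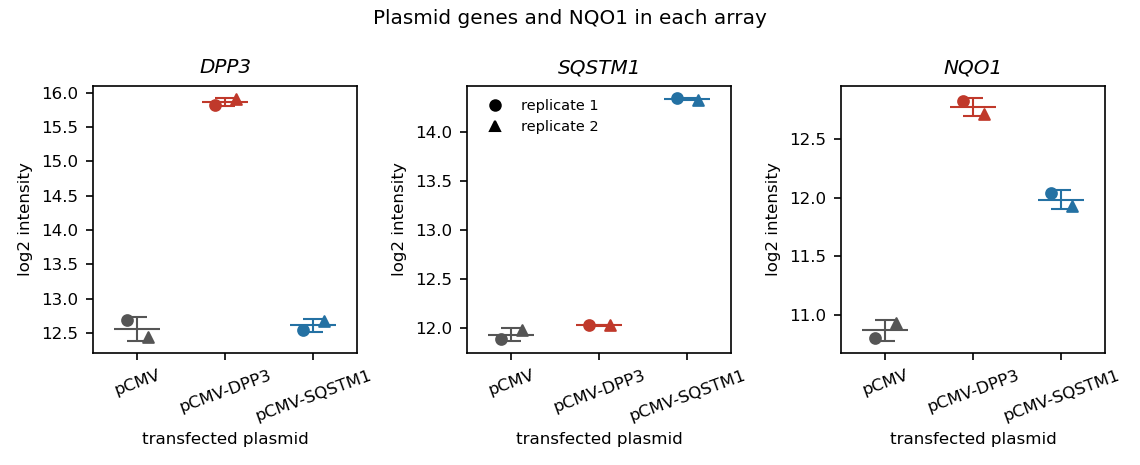
Log2 intensity (vertical axes) of DPP3, SQSTM1 and NQO1 in the 6 arrays by transfected plasmid (horizontal axes), with circles for replicate 1, triangles for replicate 2, and bars for the mean ± SD of 2 arrays. Each plasmid gene is high in its own group alone (DPP3 15.87, SQSTM1 14.34), and NQO1 is highest with DPP3 (12.77), intermediate with SQSTM1 (11.98) and lowest with pCMV (10.87).

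In cells given the SQSTM1 plasmid, SQSTM1 rose 5.31-fold over the empty plasmid, to 14.34 ± 0.01 on the log2 scale from 11.93 ± 0.06 (SD, n = 2). NQO1 was 2.16-fold higher, at 11.98 ± 0.08 (SD, n = 2), with no overlap between the arrays of the groups. ME1 and TXNRD1 were higher by 0.34 ± 0.06 and 0.24 ± 0.07 (SE) on the log2 scale, with 0.12 for TXNRD1 when averaged with its other, dim probe set. GCLM, SRXN1, HMOX1 and GCLC differed by -0.01 ± 0.06, 0.14 ± 0.06, 0.09 ± 0.13 and 0.13 ± 0.17. The other GCLM probe sets gave 0.22 ± 0.12 and 0.0045 ± 0.14. DPP3 differed by 0.05 ± 0.10.

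SQSTM1 was the only gene called of 19775, with a log2 fold change of 2.41 ± 0.04 (SE) and an adjusted p = 0.00475, while 760 genes had an unadjusted p under 0.05 against 989 expected by chance. Among the other 4 SQSTM1 probe sets, 3 lay below log2 8 and differed by at most 0.02, and 1 differed by 0.18 ± 0.08. The next smallest p-values, none of which passed, included 5 genes also among the 10 smallest with DPP3. These were FLVCR1-DT (1.02 ± 0.06), ADARB1 (0.45 ± 0.03, but 0.05 when its probe sets were averaged), ANKRD33B (0.62 ± 0.04), NQO1 (1.11 ± 0.07, adjusted p = 0.329) and SMAD3 (-0.40 ± 0.04, -0.23 when averaged). The others were PIEZO1, a mechanically gated ion channel below log2 8, with 0.71 ± 0.06 (0.24 when averaged), MATCAP1, a tubulin carboxypeptidase, with 0.53 ± 0.05, PABPC5 with 0.39 ± 0.04 and BOD1L1, which protects replication forks, with 0.34 ± 0.02 (0.20 when averaged).

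Of the 44 ARE targets, 37 were higher with SQSTM1 than with pCMV, where the median log2 fold change over all genes was 0.011. Among lists not called, 30 of 39 interferon response genes and 4 of 13 housekeeping genes were higher. Of the ARE targets, 0 passed over all genes in limma, with 6 at an unadjusted p under 0.05. Adjusted over the ARE list alone NQO1 rose (adjusted p = 0.00367) and 0 fell. Camera shifted the list up (median log2 fold change 0.10, adjusted p = 3.7e-04), with an adjusted p = 0.987 with an estimated correlation and a median of 0.021 without pCMV replicate 2, 0.025 with all probe sets and 0.056 with the mean of probe sets. The p53 targets were shifted up as well (17 of 21 higher, median 0.19, adjusted p = 0.00289), with an adjusted p = 0.987 with an estimated correlation and a median of 0.065 without pCMV replicate 2. BAX again had the smallest p, at 0.63 ± 0.14 (SE). The heat shock response was shifted down (14 of 21 lower, median -0.02, adjusted p = 0.0360), with an adjusted p = 0.987 with an estimated correlation. Its smallest p belonged to FKBP4, a co-chaperone of HSP90, at -0.18 ± 0.05. ME1 rose and ME3 fell within pentose phosphate and NADPH supply adjusted over the list alone, with log2 fold changes of 0.34 ± 0.06 and -0.23 ± 0.04. In the other 19 lists 0 members passed, and the 18 lists not called had adjusted p-values from 0.0948 to 0.986. Camera pointed down while the median was above 0 for glutathione metabolism, pentose phosphate and NADPH supply, the ATF4 and amino acid response, the cell cycle and the noradrenergic and mesenchymal markers, and the mean was below 0 for the noradrenergic markers alone among these 6. BECN1, which starts autophagosome formation, had the smallest p among autophagy and lysosome genes (0.19 ± 0.03, but 0.085 when its probe sets were averaged), and TXN, thioredoxin, that of its list (0.19 ± 0.04, but 0.069). Without pCMV replicate 1 the ARE and p53 calls ended although the medians were larger (0.16 and 0.25, adjusted p = 0.475 and 0.570), and the heat shock call ended with its median above 0 (0.014, adjusted p = 0.172). The p53 call also ended without SQSTM1 replicate 1 (adjusted p = 0.614, median 0.091), with all probe sets (0.433, median 0.021) and with the mean of probe sets (0.171, median 0.053), and the heat shock call without pCMV replicate 2 (0.348, median -0.058) or SQSTM1 replicate 2 (0.337, median 0.011), after centring (0.169), above log2 6 (0.0736), with the replicate block (0.0543) and with the mean of probe sets.

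The call of SQSTM1 ended with the replicate number as a block (adjusted p = 0.112), with only the 4 arrays compared (0.103), without either DPP3 array (0.103) and without SQSTM1 replicate 1 or 2 (0.275 and 0.270), within a range of 0.00219 to 0.275 over 20 alternatives, while the log2 fold change stayed between 2.40 and 2.41 in these settings. Averaging all 5 probe sets gave a log2 fold change of 0.52 (adjusted p = 0.188). Within station 1 SQSTM1 was higher by 2.31 ± 0.04 (SE) with SQSTM1 than with DPP3, and it differed by 0.10 ± 0.04 between DPP3 and pCMV. Without pCMV replicate 1, 68 genes rose and 121 fell against the deviating pCMV replicate 2 alone, whereas only SQSTM1 was called without pCMV replicate 2, and for the other genes the fluidics station and the plasmid cannot be told apart by this comparison alone.

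**Figure D3:**
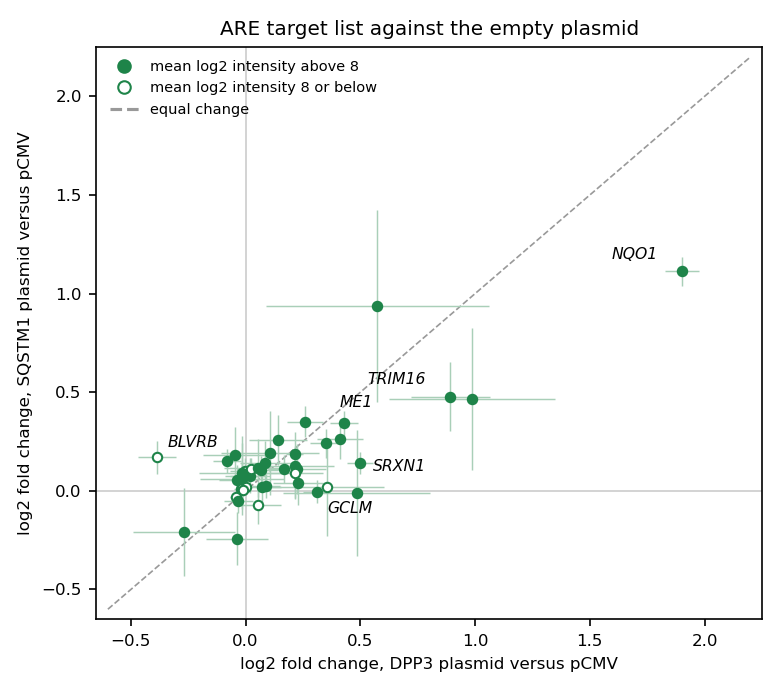
Log2 fold change against pCMV of the 44 measured ARE targets with the DPP3 plasmid (horizontal axis) and with the SQSTM1 plasmid (vertical axis), with bars of ± 1 SE, open circles for genes with a mean log2 intensity of 8 or below, and a dashed line of equal change. NQO1 lies farthest out, at 1.90 and 1.11, and most other members lie near 0.

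Between the plasmids, SQSTM1 rose by 2.31 ± 0.04 (SE) on the log2 scale and DPP3 fell by 3.25 ± 0.10, each in the direction of its own plasmid. NQO1 was lower with SQSTM1 than with DPP3, with a log2 fold change of -0.79 ± 0.07 and no overlap between the 2 arrays of each group. SRXN1 (-0.36 ± 0.06) and GCLM (-0.32 ± 0.06) were lower as well, and BLVRB was higher (0.56 ± 0.08). The other GCLM probe sets gave -0.31 ± 0.14 and -0.07 ± 0.12. TXNRD1, GCLC and HMOX1 differed by -0.11 ± 0.07, -0.09 ± 0.17 and -0.12 ± 0.13, within 2 standard errors.

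SQSTM1 and DPP3 were the 2 genes called of 19775 (adjusted p = 0.00563 and 0.0421). An unadjusted p under 0.05 was reached by 505 genes in limma over all 6 arrays, where 989 were expected by chance. With only the 4 arrays of these groups, whose spread excludes the pCMV arrays, 1979 genes reached it. NQO1 did not pass over all genes (adjusted p = 0.816). Of the 10 smallest p-values, those of PIEZO1 (0.74 ± 0.06), MPP1 (0.56 ± 0.05), PABPC5 (0.45 ± 0.04), BOD1L1 (0.26 ± 0.02) and HELLS, a chromatin remodeller (0.35 ± 0.03), belonged to genes higher with SQSTM1. ANKRD33B (-0.38 ± 0.04) and ATRNL1 (-0.26 ± 0.03) were lower. None of these 7 passed, and averaging each gene's probe sets gave 0.25 for PIEZO1, 0.078 for BOD1L1, 0.090 for HELLS and -0.047 for ATRNL1. The groups did not overlap for 56.5% of genes, where chance gives 33.3%, against 18.1% in DPP3 against pCMV and 24.5% in SQSTM1 against pCMV.

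Of the 44 ARE targets, 0 passed over all genes in limma, with 5 at an unadjusted p under 0.05, and adjusted over the list alone BLVRB rose and NQO1 and SRXN1 fell (adjusted p = 0.0443, 0.0148 and 0.0443). Camera shifted the list down (adjusted p = 0.00317), although the median log2 fold change was 0.01 and 23 members were higher, while the mean was -0.05, and the adjusted p was 0.625 with an estimated correlation. Glutathione metabolism was shifted down (median -0.02, 14 of 35 higher, adjusted p = 0.00245), with an adjusted p = 0.564 with an estimated correlation, and GCLM had its smallest p. GCLM and other members are also ARE targets, so the call is not separate from that of the ARE list. BLVRB also rose within iron and haem handling adjusted over the list alone (adjusted p = 0.0467). In the other 19 lists 0 members passed, and the 19 lists not called, p53 targets among them, had adjusted p-values from 0.0744 to 0.992. Besides the ARE targets, camera pointed down against the sign of the median or the mean for thioredoxin, pentose phosphate, unfolded protein, ATF4, autophagy, p53, immediate early, hypoxia and mesenchymal genes. The ARE call ended without DPP3 replicate 2 (adjusted p = 0.478) or SQSTM1 replicate 1 (adjusted p = 0.0505), and so did the glutathione call (adjusted p = 0.453 and 0.0509), which also ended after centring (0.0631). The glutathione median turned to 0.023 without DPP3 replicate 2 and was -0.0083 without SQSTM1 replicate 1 and -0.049 without DPP3 replicate 1.

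Within their station, by the 4 arrays of these groups alone, SQSTM1 was called (1 of 19775 genes), and DPP3 was not (adjusted p = 0.429). With the replicate block the adjusted p-values of SQSTM1 and DPP3 were 0.128 and 0.609, while the log2 fold changes were 2.31 and -3.25 in both fits, and without each of the 6 arrays in turn 0 or 1 gene was called, with ranges over 20 alternatives of 0.00140 to 0.615 for SQSTM1 and 0.00140 to 0.733 for DPP3.

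The comparisons with pCMV share its 2 arrays, so their fold changes correlate without any effect. Across the 19775 genes, which are not independent replicates, the log2 fold changes of DPP3 and SQSTM1 had a Pearson correlation of 0.60, where 100 simulations of unchanged groups with shared controls gave a mean of 0.50 and a maximum of 0.54. Their covariance was 0.0119 against a simulated mean of 0.0111 and maximum of 0.0125. The 10 smallest p-values of each comparison shared ANKRD33B, NQO1, SMAD3, FLVCR1-DT and ADARB1, all 5 in the same direction, where simulation gave a mean of 2.55 shared genes and a maximum of 5, and independent lists would share 0.00506. The simulation gave each gene 1 SD in all groups and let all arrays vary independently. Above log2 8 the median SD between arrays was 0.12 for pCMV, 0.10 for DPP3 and 0.06 for SQSTM1, and 2 arrays deviated together. The simulated values thus do not settle whether the correlation or the overlap exceeds what shared controls give. With 1 pCMV array as the control of each plasmid, a comparison chosen after seeing the data, no control is shared. The correlation was then -0.266 with pCMV replicate 1 for DPP3 and 2 for SQSTM1, and 0.0521 in the reverse order. In the first order the deviation common to pCMV replicate 2 and DPP3 replicate 1 enters the 2 fold changes with opposite signs. The value of -0.266 therefore does not show whether the plasmids share an effect. Without pCMV replicate 1 the correlation was 0.850, and without DPP3 replicate 2 it was 0.205.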

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

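The filter at log2 above 8, the term for 2 arrays, the crossed pairing, the loss of both deviating arrays and the separate controls were chosen after seeing the data. The 2 arrays per group limit the precision. Genes under log2 8 lie nearer to background, and leaving them out also tests fewer genes. The cause of the other changes was not tested. A station block could not be fitted against pCMV and was not run. For 104 results on named genes, 1987 of 2059 values kept their direction and their side of the threshold, 32 lost and 23 gained the call, 17 uncalled values changed sign, and 0 called values reversed. These values are not separate checks. The setting without a filter repeated the main fit. Leaving out either array of the group not compared repeated the fit of only the arrays compared. The replicate block left the fold changes as they were. Most of these results lay far above the threshold in the main fit, so staying uncalled was likely beforehand. The tally therefore does not measure robustness.

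For DPP3 against pCMV, where 0 genes were called, 2 were called after centring on array medians (DPP3 and ANKRD33B), 1 with log2 above 6 (DPP3), 3 with the mean of probe sets (DPP3, NQO1 and ANKRD33B), 2 with an intensity trend and robust prior, 3 at an adjusted p of 0.10 and 2 with log2 above 8. For SQSTM1 against pCMV, where 1 was called, 0 were with the mean of probe sets and 0 with only the 4 arrays compared (723 and 915 unadjusted p-values under 0.05). For SQSTM1 against DPP3, where 2 were called, 1 was with quantile normalization, 1 with all probe sets, 1 with the mean of probe sets and 1 with the 4 arrays (1979 unadjusted p-values under 0.05 in the last). With the term for the 2 arrays that deviate together, and without both of these arrays, 0 genes were called in every comparison; unadjusted p-values under 0.05 then numbered 1393 and 5747, 1096 and 3608, and 850 and 3690. Leaving out each array in turn gave from 0 to 206 genes for DPP3 against pCMV, 0 to 189 for SQSTM1 against pCMV (both highest without pCMV replicate 1) and 0 to 1 for SQSTM1 against DPP3. A group left with 1 array was assumed to vary like the others.

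Whether the replicate numbers pair the samples was not settled by these arrays. Over 9846 genes, the deviations of arrays with the same number correlated at -0.52 between pCMV and DPP3. The values were 0.11 between pCMV and SQSTM1 and -0.01 between DPP3 and SQSTM1. The value of -0.52 does not test pairing, because pCMV replicate 2 and DPP3 replicate 1 deviate together under different numbers. With the number as a replicate block, 0 genes were called in each comparison, at 664, 738 and 525 unadjusted p-values under 0.05, and 7 of the 63 list tests were called against 8; the list call lost was that of the heat shock response. With the paired numbers crossed for DPP3, 0, 0 and 0 genes were called.

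The shift of the ARE list kept its camera direction in every setting. Its median log2 fold change ranged from 0.024 to 0.18 for DPP3, from 0.021 to 0.16 for SQSTM1 and from -0.040 to 0.019 between the plasmids when each array was left out, with adjusted p-values from 2.8e-09 to 0.0969, 2.4e-04 to 0.475 and 6.0e-06 to 0.478. With all probe sets it was 0.015, 0.025 and 0.016, and with the mean of probe sets 0.054, 0.056 and -0.0088. The medians of 0.079, 0.10 and 0.011 had adjusted p-values of 0.667, 0.987 and 0.625 with an estimated correlation and of 0.407, 0.532 and 0.983 with fry. Between the plasmids the call also ended with quantile normalization (median -0.0076, adjusted p = 0.0666) and centring (median -0.017, adjusted p = 0.222). Over all 63 list tests, 8 were called, against 16 with all probe sets, 18 with only the 4 arrays, 25 without both deviating arrays, 5 to 22 without each array, and 0 with an estimated correlation or fry. The correlation of the fold changes ranged from 0.205 to 0.850 when each array was left out, and was -0.266 and 0.0521 with 1 pCMV array as the control of each plasmid, in both orders.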

Other observations

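All tests of explanations given here were chosen after the results were seen. Single members of lists that did not shift stood out by their p alone and did not pass. VEGFA, the vascular growth factor of the hypoxia list, differed from pCMV by 0.56 ± 0.12 (SE) on the log2 scale with DPP3 and 0.63 ± 0.12 with SQSTM1, with no overlap between arrays in either comparison, but by 0.15 and 0.11 when its 4 probe sets were averaged. MAP1LC3A, a component of autophagosome membranes, differed by -0.61 ± 0.14 with DPP3 (-0.41 when its probe sets were averaged) and by -0.67 ± 0.14 with SQSTM1. KLF4, an immediate early transcription factor with intensities below log2 8, differed by 0.35 ± 0.07 with DPP3 and by -0.40 ± 0.07 between SQSTM1 and DPP3, and by 0.14 and -0.19 when its probe sets were averaged. The serine synthesis gene PSAT1 (-0.22 ± 0.04) and the last enzyme of one route to cholesterol, DHCR7 (-0.27 ± 0.06), had the smallest p of their lists with DPP3.

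The interferon response list, of which 6 of 39 measured members exceeded log2 8, had 30 members higher in both SQSTM1 arrays than in both DPP3 arrays and 0 lower, with a median log2 fold change of 0.02. Over all genes the median was 0.022 as well, and the groups did not overlap for 56.5% of genes, where chance gives 33.3%. Camera did not call the list (adjusted p = 0.205). Of the 34838 probe sets outside the set of 1 per gene, 0 were called higher with either plasmid. Those not called include the second DPP3 probe set with the DPP3 plasmid (3.54 ± 0.10, adjusted p = 0.0883 in limma over all probe sets). The absence of calls therefore does not show that the others were unchanged.

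pCMV replicate 2 and DPP3 replicate 1 deviated together from the other 4 arrays although they belong to different groups. Degraded RNA would raise the 3' signal of ACTB and GAPDH over the 5' signal, but the mean difference was lower in both arrays than in the others, by -0.15 on average on the log2 scale. Exchanged labels are argued against by DPP3, which was 3.39 higher in the array labelled DPP3 replicate 1 than in pCMV replicate 2. A different amount of labelled RNA or a difference in hybridisation stays open: in the hybridisation spike-ins the lower of the 2 arrays lay 0.60 above the highest of the others, but this gap is part of the pattern itself and decides nothing. No biological explanation was tested.

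NQO1 and the ARE list were higher in both plasmid groups than in pCMV, which was washed on another station. NQO1 differed by -0.79 ± 0.07 (SE) between SQSTM1 and DPP3, which shared a station. This argues against the station as the whole cause of both NQO1 differences from pCMV. For either difference taken alone, station and plasmid cannot be told apart, and a partial contribution stays open. The shared deviation of 2 arrays as the cause of the NQO1 difference is argued against by SQSTM1 against pCMV. The NQO1 log2 fold change there was 1.17 ± 0.06 with a term for these arrays. For the ARE list with SQSTM1 the shared deviation stays open, since that term left a median of 0.041 against 0.10. With DPP3 the median was 0.079 with and without the term. The deviating arrays lie in opposite groups of that comparison, so an equal deviation cancels and this value does not test it. For the shift of the ARE list, station and plasmid cannot be told apart, because both pCMV arrays were washed on another station than all plasmid arrays. Between SQSTM1 and DPP3, which shared a station, camera called the list at the preset correlation (adjusted p = 0.00317). At an estimated correlation camera did not call it (adjusted p = 0.625), which does not show that the list was equal. An effect of the plasmids is the biological explanation the design names, and it stays open.

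A second SQSTM1 probe set was higher with the DPP3 plasmid than with pCMV, by 0.60 ± 0.08 (SE) on the log2 scale, and by 0.18 ± 0.08 with the SQSTM1 plasmid, and was chosen after its values were seen. A rise of the whole SQSTM1 transcript pool is argued against by the main probe set, which differed by 0.10 ± 0.04. The shared deviation of 2 arrays is argued against by the difference of 0.021 between the 2 DPP3 arrays, both above the other 4. A transcript form that this probe set reads alone, whether or not it depends on DPP3, may remain as a hypothesis, and it was not tested because no probe positions were used here.

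A further hypothesis was that DPP3 raised ARE targets in general further than SQSTM1 did. Of the 33 members above log2 8, 18 were lower with SQSTM1 than with DPP3, an exact two-sided binomial p = 0.728. That test takes higher and lower as equally likely, whereas the median log2 fold change over all genes was 0.022. Its baseline thus does not match these data, and it does not decide the question. Genes of a list are not independent.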
